A study of Bos taurus with 6 samples.

How the data were processed

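Gene expression was measured with two-colour oligonucleotide arrays in bovine capillary endothelial cells from the adrenal medulla, treated with tunicamycin or left as control for 3 or 32 h. On each array, labelled RNA from tunicamycin cells in one dye was hybridised together with labelled RNA from control cells in the other dye, so an array gives a ratio and carries its own control. Per the labels, 6 arrays were used, 3 at each time. At 3 h, tunicamycin RNA was in Cy5 on 1 array (R2) and in Cy3 on 2 arrays (S1 and S2). At 32 h it was likewise in Cy5 on 1 array (R1) and in Cy3 on 2 (S1 and S2). Per the series' design text, the dye swaps were made with different biological replicates. The 2 further arrays that completed the design did not pass the authors' quality control and were not analysed here. One slide carried 32 h R1, 3 h S1 and 32 h S1 (slide 1), and another carried 3 h R2, 3 h S2 and 32 h S2 (slide 2). The slide coincides with the number in the labels and with the extraction protocol, so these cannot be told apart from each other, but each slide holds arrays of both times.

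Per the file headers, the authors extracted the intensities with Agilent Feature Extraction 9.5.3.1, with an older protocol on slide 1 and a newer one on slide 2. Only the newer protocol applied multiplicative detrending, and its multiplier for calling a spot well above background was 13 against 2.6 on slide 1. The deposited scanner files give, for each spot and channel, mean and background intensities, and log10 ratios of Cy5 over Cy3 made by the scanner software from its background-subtracted and dye-normalized signals. The authors' table of values holds 1 log2 value per probe and array, and no source used here states its scale, centring or direction. Set against the scanner intensities, its columns had slopes from 0.996 to 1.00 and correlations across probes from 0.966 to 0.998 with log2 ratios of tunicamycin over control after loess without background subtraction. The medians of its columns lay between -0.0031 and 0.0041. Its scale, centring and direction were taken from this match.

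Mean intensities were corrected with the normexp method (offset 50) against the median local background, and each array was normalized by loess with weight 0 for control spots, with limma 3.58.1 in R 4.3.3. Spots called outliers by the scanner software were left out. Ratios were turned to log2 of tunicamycin over control by the dyes in the labels, and spots of a probe were averaged. Of 21475 probes, 16917 were tested. These were well above background in at least 1 channel on at least 3 of the 6 arrays, and 1 further probe was left out for lack of a usable spot on an array. Array signals have no read depth. The number of arrays limits the precision, and log ratios of dim probes are drawn towards 0 by the offset.

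Probes were named through a table of current bovine genes (assembly ARS-UCD2.0), which was used only for names since the array design is older and names no build. Of the probes, 3504 were matched by accession, 9611 by a gene number in the files, 3762 through a description naming a human homologue, 167 through another description and 5 through the gene name column, and 4426 stayed unnamed. For a gene with several probes, the probe with the highest mean intensity stood for it, which left 12758 genes.

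All 6 arrays entered 1 limma fit (lmFit and eBayes, two-sided) with an effect of tunicamycin for each time and 1 dye effect shared by both times, which leaves 3 residual degrees of freedom. From it came 4 contrasts: the effect at 3 h, at 32 h, their average, and 32 h minus 3 h. A probe passed at a Benjamini-Hochberg adjusted p under 0.05. The 30 gene lists and 4 as the smallest number of measured members, the settings, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with limma's camera (preset inter-gene correlation 0.01), with adjustment over the 30 lists. It asks whether the mean z of a list's genes, from the moderated t, lies above or below that of the other genes. The p of camera does not measure the spread between arrays, and the n beside it is the number of arrays of that time. Counts of list members above or below 0 are of fitted values unless arrays are named. Camera with an estimated correlation, and limma's fry, which asks whether a list's genes move one way without comparing them with other genes, were run beside it.

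By the rule, the genes named at a time are the 10 with the largest rise and the 10 with the largest fall past the threshold, in the same direction on all 3 arrays. Where fewer than 5 genes pass, they are the 10 with the smallest p, given as not past the threshold. Up to 4 members with the smallest p are named from each list described, and 15 genes of the tunicamycin response, the cell cycle, endothelium and angiogenesis are given at both times. Members named from lists that did not pass, and genes called under an alternative, were chosen after their values were seen.

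The procedure was tested on simulated log ratios with the probes' own residual spreads and no slide effect. For a change of 1 on the log2 scale, 54.0% of 100 simulated probes were recovered at 3 h and 57.0% at 32 h, among 16917. For a change of 2 on the log2 scale, 89.0% were recovered at 3 h and 84.0% at 32 h. False calls made up 4.03% of calls at 3 h and 1.40% at 32 h.

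The alternatives covered background correction, normalization, the authors' table, the filter on dim probes, the dye term, the slide as a fixed or random block, a dye term for each slide, fits of each time alone, the dye-balanced pair of arrays that each time has on 1 slide, array weights, a trended and robust eBayes, other thresholds, and leaving out each array in turn. A fit without both swap arrays of slide 2, and one with the 4 swap arrays turned to the orientation of the other 2 and no dye term, since dye and treatment then coincide, were added after seeing the data. Leaving out 32 h R1 or 3 h R2 leaves that time only arrays with tunicamycin in Cy3. The dye term that corrects them then comes from the other time alone, so such fitted values can lie outside those of the arrays left.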

Results

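Tunicamycin blocks the first step in the synthesis of the glycan that is attached to asparagine residues of new proteins in the endoplasmic reticulum (ER), and unglycosylated proteins that fail to fold there set off the unfolded protein response. Capillary endothelial cells line the smallest vessels, and the design text names the arrays for angiogenesis, the growth of new vessels. RNA of tunicamycin and control cells was compared on 3 arrays after 3 h and on 3 after 32 h. Between 65.2% and 78.2% of probes were well above background in a channel, and no spot was saturated. Median intensities of a channel lay between 189.6 and 530.8. Repeat spots of a probe correlated with r from 0.767 (3 h R2) to 0.968 (32 h R1) across probes, and the standard deviation of the log2 ratio over probes ran from 0.17 on 3 h R2 to 0.41 on 32 h S1.

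Tunicamycin ratios as labelled did not group by time. Across 16917 probes, which are not independent replicates, arrays of 1 slide with tunicamycin in opposite dyes correlated negatively in all 4 pairs (median r = -0.55, from -0.67 to -0.31). Arrays of 1 slide with tunicamycin in the same dye correlated with r = 0.41 and r = 0.69. Arrays on different slides had a median r of 0.01 over 9 pairs. The 6 pairs of the same time had a median r of -0.15, but 32 h R1 with 32 h S1 and 3 h R2 with 3 h S2 (r = -0.55 each) share a slide with opposite dyes. Pairs of the same time on different slides had r of -0.20, 0.31, -0.11 and 0.01, and as Cy5 over Cy3 0.20, 0.31, 0.11 and 0.01. As Cy5 over Cy3, pairs differing in time and slide had r of -0.03, -0.17, 0.22, -0.13 and -0.05. This contrast was not tested. The direction of every ratio, and every count above or below 0, is that of the dyes in the labels. In a fit with the 4 swap arrays turned, which can hold no dye term, none of the 8 list calls at 3 and 32 h kept both its direction and its side of the threshold. Targets of ATF4 and CHOP then had medians of -0.04 at 3 h (12 of 26 above 0, adjusted p = 0.647) and -0.03 at 32 h (11 of 26, adjusted p = 0.941, with camera's direction up). At 32 h ER chaperones fell (median -0.15, adjusted p = 0.0347) and ribosomal proteins rose (median 0.12, adjusted p = 0.0072) in that fit, where limma again called 0 probes, with 1722 at 3 h and 3769 at 32 h at an unadjusted p under 0.05. TRIB3, above 0 on 1 of 3 arrays at 3 h as labelled, would then lie above 0 on 3 of 3.

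**Figure D1:**
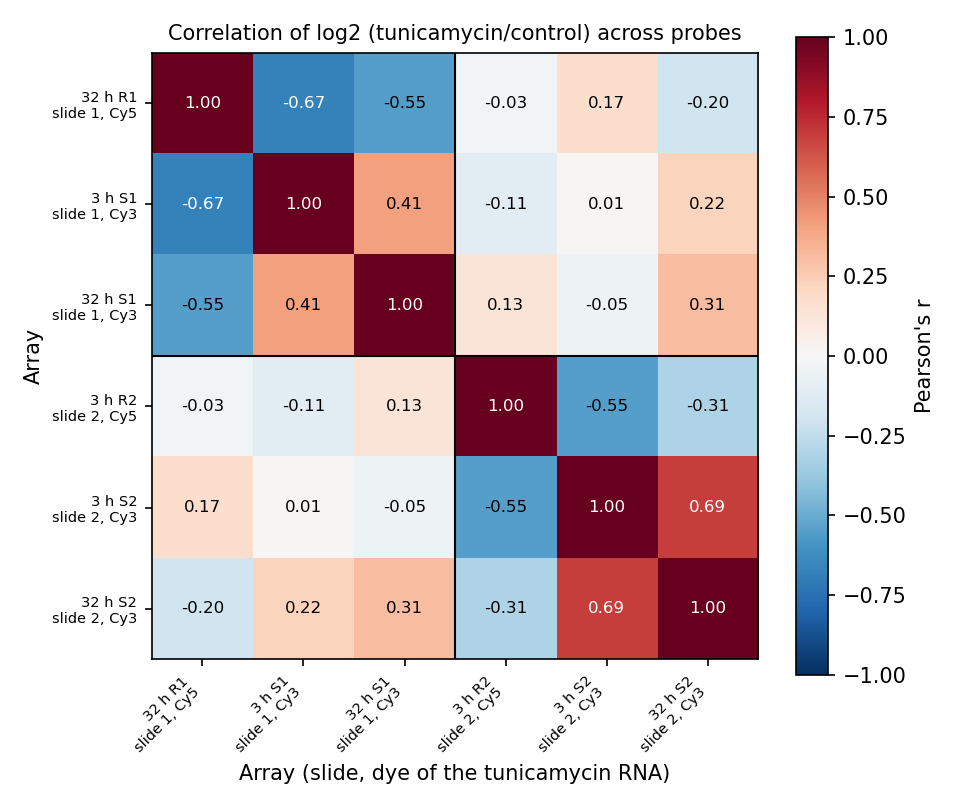
Pearson's r of the log2 ratio of tunicamycin over control across 16917 probes for each pair of the 6 arrays, ordered by slide (black lines) and by the dye of the tunicamycin RNA. The 4 pairs on 1 slide with opposite dyes lie between -0.67 and -0.31, and the 9 pairs on different slides between -0.20 and 0.31.

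After 3 h, targets of ATF4 and CHOP, the transcription factors that act downstream of the kinase PERK when translation is curbed, rose as a group. Of the 26 measured members 24 had fitted values above 0, with a median log2 change of 0.17 (camera adjusted p = 2.6e-11, n = 3 arrays), while the other genes averaged -0.0011. For this list adjusted p = 0.978 with an estimated correlation, where the estimate was 0.16. On single arrays 13 (S1), 18 (R2) and 17 (S2) of the 26 lay above 0. TRIB3, a pseudokinase induced by CHOP, stood at 0.45 ± 0.10 (SE) on the log2 scale, a fold of 1.37, and the stress-induced regulators of mTORC1 DDIT4 and SESN2 at 0.63 ± 0.26 and 0.42 ± 0.16. CEBPB, a transcription factor of the same bZIP class as ATF4, stood at 0.32 ± 0.13. DDIT4, SESN2 and CEBPB lay above 0 on all 3 arrays, and TRIB3 on 1 of 3, at 0.94 on R2 against -0.13 on S1 and -0.06 on S2. Without 3 h R2 the fitted value of DDIT4 was -0.05 and that of SESN2 0.18, and without 3 h S1 that of CEBPB was 0.19. Another probe of SESN2, with a mean log2 intensity of 11.4 against 13.7, stood at 0.09.

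None of these members passed on its own. With limma, 0 of 16917 probes passed at 3 h, and 64 had an unadjusted p under 0.05, fewer than the 845.8 that chance would give. Adjusted over the list alone, 0 of the 26 targets passed as well, against 2 with an unadjusted p under 0.05. By fry the list had adjusted p = 0.980. With the slide as a block the median was 0.19 (adjusted p = 1.0e-13). Within slides the median was 0.16 on slide 2, which holds both dyes at 3 h, and 0.0069 on the single 3 h array of slide 1.

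Genes of mitosis also rose as a group at 3 h, with 26 of 32 members above 0 and a median of 0.08 (camera adjusted p = 0.00035, n = 3). For mitosis adjusted p = 0.978 with an estimated correlation. KIF20A, a kinesin of cytokinesis, stood at 0.39 ± 0.15 (SE), the kinase PLK1 at 0.29 ± 0.16, the checkpoint kinase BUB1B at 0.36 ± 0.22 and the phosphatase CDKN3 at 0.31 ± 0.19. Without 3 h S1 PLK1 stood at 0.09 and CDKN3 at 0.05, without 3 h S2 BUB1B at 0.06, and without 3 h R2 KIF20A at 0.61. The list median was largest on array S1, at 0.55, against 0.06 on R2 and -0.10 on S2. Without 3 h S1 and in the dye-balanced pair the direction turned (adjusted p = 0.655 and 0.4998), without 3 h R2 it was lost (0.346), and with a dye term for each slide adjusted p = 0.514. Within slides the median was 0.55 on slide 1 and 0.00038 on slide 2, and with the slide as a block 0.12 (adjusted p = 1.8e-08), while the call was lost with the slide as a random block (adjusted p = 0.0549). None of the 32 members passed over all genes or adjusted over the list alone (0 and 0), and 1 had an unadjusted p under 0.05 in limma.

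Genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, fell as a group at 3 h, with 35 of 46 members below 0 and a median of -0.07 (camera adjusted p = 0.00064, n = 3). This list had adjusted p = 0.978 with an estimated correlation. The complex I subunit NDUFA5 stood at -0.44 ± 0.15 (SE), the ATP synthase subunit ATP5PF at -0.15 ± 0.09 and the complex IV subunit COX7A2 at -0.17 ± 0.12, each below 0 on all 3 arrays. Another subunit of complex IV, COX6B1, stood at 0.22 ± 0.13 and above 0 on all 3. Without 3 h R2 the fitted value of COX7A2 was 0.04 and that of NDUFA5 -0.27, and without 3 h S1 that of COX6B1 was 0.09. In limma 0 of 46 passed over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The group's call was lost without 3 h R2 (adjusted p = 0.512), without 3 h S2 (0.678), with processed signals (0.0629) and with array weights (0.975), and turned upwards with median centring (0.784). Within slides the median was -0.07 on slide 1 and -0.11 on slide 2, and with the slide as a block -0.06 (adjusted p = 0.0099).

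Of single genes at 3 h, the 10 with the smallest p are given as not past the threshold (adjusted p = 1 for each, n = 3). CREG1, a secreted glycoprotein of the endolysosomal pathway, stood at -0.68 ± 0.13 (SE), a fold of 0.623, below 0 on all 3 arrays. HERPUD1, a membrane protein of ER-associated degradation, stood at 0.57 ± 0.15, above 0 on all 3, with 1.19 on R2 and 0.02 and 0.12 on S1 and S2, and at 0.25 without 3 h R2. Besides TRIB3, the others above 0 were SH3BP5L (0.43 ± 0.11), ZBTB22 (0.37 ± 0.11), PKP4 (0.36 ± 0.10) and MFAP3L (0.32 ± 0.10, well above background on 2 of 3 arrays, and 0.18 without 3 h R2). Those below 0 were MYL9, a myosin light chain (-0.43 ± 0.13), ZNF24 (-0.43 ± 0.12) and SUSD2 (-0.31 ± 0.09). A dimmer probe of SH3BP5L stood at 0.26.

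The ER chaperone HSPA5 (BiP), a standard marker of ER stress, stood at 0.29 ± 0.39 (SE, n = 3) at 3 h, with 0.97 on R2, 0.16 on S1 and -0.74 on S2. HSP90B1 stood at 0.08 ± 0.20, DDIT3, which encodes CHOP, at 0.27 ± 0.14, ATF4 at 0.03 ± 0.18, ATF3 at 0.17 ± 0.10, ASNS at 0.12 ± 0.14 and XBP1 at 0.01 ± 0.15. DPAGT1, the enzyme that tunicamycin blocks, stood at -0.03 ± 0.15. CCND1 stood at -0.23 ± 0.20 and CDKN1A at 0.07 ± 0.14. The endothelial genes KDR and PECAM1 stood at 0.05 ± 0.09 and 0.16 ± 0.11, and the angiogenic factor VEGFA at 0.03 ± 0.11. Without 3 h R2 HSPA5 stood at 0.02, and without 3 h S2 DDIT3 stood at 0.13, CCND1 at -0.12 and ASNS at 0.00034. None of these passed. With the swap arrays as labelled, the values of ATF4, XBP1, DPAGT1, CDKN1A, KDR, PECAM1, VEGFA and HSP90B1 changed sign under at least 1 alternative setting or without 1 array.

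**Figure D2:**
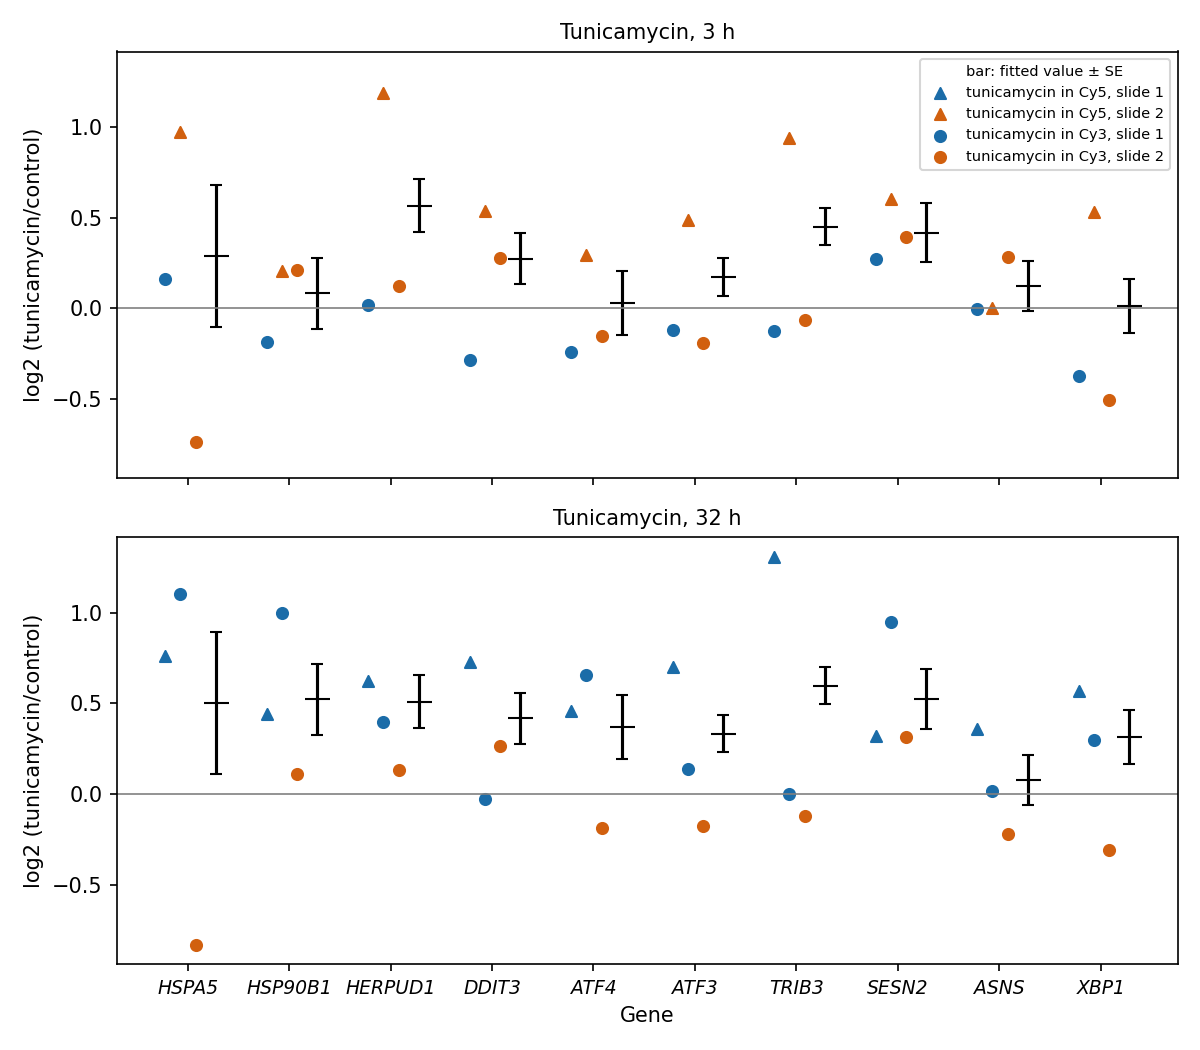
Log2 ratio of tunicamycin over control for 10 genes of the ER stress response on each array at 3 h (top) and 32 h (bottom), with marker shape for the dye of the tunicamycin RNA and colour for the slide. Black bars give the fitted value ± SE. HSPA5 lies at 0.97 on 3 h R2 and at -0.74 on 3 h S2, and SESN2, shown by the brighter of its probes, lies above 0 on all 6 arrays.

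After 32 h, targets of ATF4 and CHOP again rose as a group, with 23 of 26 members above 0 and a median log2 change of 0.17 (camera adjusted p = 8.3e-08, n = 3 arrays), against a mean of 0.0056 for other genes. The targets had adjusted p = 0.575 with an estimated correlation. On single arrays 21 (R1), 20 (S1) and 11 (S2) of the 26 lay above 0. TRIB3 stood at 0.60 ± 0.10 (SE), a fold of 1.51, and was the 1 target to pass when adjusted over the list alone, against 0 over all genes tested. SESN2 stood at 0.52 ± 0.16, and PSPH, the last enzyme of serine synthesis, at 0.49 ± 0.12, both above 0 on all 3 arrays. ATF3 stood at 0.33 ± 0.10. TRIB3 lay at 1.31 on R1, 0.00082 on S1 and -0.12 on S2. Its fitted value of 0.46 without 32 h R1 lies above both arrays left, as its dye term then comes from the 3 h arrays alone. The other probe of SESN2, with a mean log2 intensity of 11.4 against 13.7, stood at 0.08, and the brighter one was at 0.32 without 32 h S1.

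ER chaperones and folding enzymes rose as a group at 32 h, with 16 of 21 members above 0 and a median of 0.19 (camera adjusted p = 0.0113, n = 3). Chaperones had adjusted p = 0.575 with an estimated correlation. HSP90B1, the ER member of the HSP90 family, stood at 0.52 ± 0.20 (SE), a fold of 1.44, the disulfide isomerase PDIA4 at 0.29 ± 0.11, the co-chaperone DNAJC3 at 0.26 ± 0.10 and the lectin CALR at 0.22 ± 0.12. HSP90B1 and DNAJC3 lay above 0 on all 3 arrays, PDIA4 and CALR on 2. HSPA5 stood at 0.50 ± 0.39, with 0.76 on R1, 1.10 on S1 and -0.83 on S2, and its fitted value was -0.03 without 32 h S1. HSP90B1 stood at 0.28 without 32 h S1 and CALR at 0.03 without 32 h R1. The list medians of the arrays were 0.10 on R1, 0.53 on S1 and 0.15 on S2, with 11, 18 and 14 of the 21 members above 0. The list means were -0.06 on R1, 0.46 on S1 and 0.18 on S2.

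In limma, 0 of 16917 probes passed at 32 h, and 499 had an unadjusted p under 0.05, of which 368 were higher, where chance would give 845.8. The share higher, 73.75% here, was 96.0% with median centring, 62.6% with a dye term for each slide and 45.6% with the 4 swap arrays turned. With median centring in place of loess 5 probes passed, all higher: PRRC2C (1.37), ABL2 (1.34), NFIL3 (1.27), ZNF326 (1.37) and a probe with no gene name (1.47), named after their values were seen. Of the 21 chaperones 0 passed over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05, against 8 of the ATF4 and CHOP targets (7 higher, 1 lower). For these lists fry gave adjusted p = 0.746 for the targets and 0.782 for the chaperones. With the slide as a block the medians were 0.20 (adjusted p = 2.4e-06) and 0.12 (adjusted p = 0.0284). On slide 1, which holds both dyes at 32 h, they were 0.22 for targets and 0.19 for chaperones, and on the single array of slide 2 -0.05 and 0.15. The call for chaperones was lost without 32 h S1 (adjusted p = 0.491), and both were lost with array weights (0.128 and 0.519).

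Genes of the interferon response fell as a group at 32 h, with 18 of 23 members below 0 and a median of -0.08 (camera adjusted p = 0.0113, n = 3). The interferon list had adjusted p = 0.685 with an estimated correlation. The ubiquitin-like modifier ISG15 stood at -0.45 ± 0.16 (SE) and its activating enzyme UBA7 at -0.41 ± 0.15, both below 0 on all 3 arrays. The immunoproteasome subunit PSMB9 stood at -0.51 ± 0.20 and XAF1 at -0.24 ± 0.11, and without 32 h R1 at -0.92 and -0.08. No member passed over all genes or adjusted over the list alone (0 and 0 of 23), and 3 had an unadjusted p under 0.05 in limma. The call was lost without 32 h R1 (adjusted p = 0.589), without 32 h S1 (0.0749), with a dye term for each slide (0.0771) and with array weights (0.130). With the slide as a block the median was -0.10 (adjusted p = 0.0284), and within slides -0.07 on slide 1 and -0.04 on slide 2.

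Genes of glycolysis and hypoxia fell at 32 h by camera (adjusted p = 0.0298), with 16 of 23 members below 0 and a median of -0.08. Their adjusted p = 0.575 with an estimated correlation. Among them, the aldolase ALDOC stood at -0.30 ± 0.10 (SE, n = 3), PFKFB4 at -0.42 ± 0.14, the glucose transporter SLC2A1 at -0.24 ± 0.13 and GPI at -0.22 ± 0.10, the first 3 below 0 on all 3 arrays. Cytosolic ribosomal proteins fell too (adjusted p = 0.0291), with 53 of 73 below 0 and a median of -0.08. For ribosomal proteins adjusted p = 0.685 with an estimated correlation. RPL7A stood at -0.27 ± 0.13, RPL30 at -0.27 ± 0.15, RPL3 at -0.22 ± 0.11 and RPS3 at -0.19 ± 0.10. Without 32 h R1 SLC2A1 stood at -0.05, GPI at -0.12, and RPL3, RPS3 and RPL30 each at -0.11. Neither call held with the slide as a fixed block (adjusted p = 0.0906 for each, medians -0.10 and -0.04), and both held with it as a random block (0.0168 for glycolysis, 0.0124 for ribosomal proteins). The within-slide medians of glycolysis were -0.06 on slide 1 and -0.12 on slide 2, and those of ribosomal proteins -0.12 and -0.08. Without 32 h R1 ribosomal proteins turned upwards (adjusted p = 0.569), and without 32 h S1 their call was lost (0.491). The glycolysis call was lost without 32 h R1 (0.282), 32 h S1 (0.101), 32 h S2 (0.0769) or 3 h S2 (0.0672). It was also lost with processed signals (0.157), median centring (0.686), no dye term (0.0588), 32 h alone (0.0516), the balanced pairs (0.0686), array weights (0.137), the mean of a gene's probes (0.083) and without both swap arrays of slide 2 (0.0897). That of ribosomal proteins was lost with processed signals (0.244), median centring (0.320), a dye term for each slide (0.120) and array weights (0.924). In limma 0 members of either list passed over all genes or adjusted over the list alone, and those with an unadjusted p under 0.05 numbered 2 and 0.

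Components of ER-associated degradation (15 of 21 above 0, median 0.07) and cytosolic aminoacyl-tRNA synthetases (15 of 19, median 0.11) had camera adjusted p = 0.0502 each at 32 h and did not pass. Their adjusted p = 0.685 with an estimated correlation. Both passed without background subtraction, with median centring, the authors' table, the strict filter, trend with robust eBayes, the slide as a random block, in the balanced pair and without 32 h S2. ER-associated degradation also passed with a dye term for each slide (0.0328) and without 32 h R1 or 3 h S1, and the synthetases with no dye term, with 32 h fitted alone and without 3 h R2 or 3 h S2. With the slide as a fixed block both had adjusted p = 0.108. HERPUD1 stood at 0.51 ± 0.15 (SE, n = 3), and the ubiquitin ligase SYVN1 at 0.73 ± 0.19. HERPUD1 lay above 0 on all 3 arrays, at 0.63 on R1, 0.40 on S1 and 0.13 on S2. Its fitted value of 0.83 without 32 h R1 exceeds each of these, as its dye term then comes from the 3 h arrays alone. The lysyl-tRNA synthetase KARS1 stood at 0.48 ± 0.19.

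Of single genes at 32 h, the 10 with the smallest p are given as not past the threshold (adjusted p = 1 for each, n = 3), and all 10 lay above 0. NFIL3, a bZIP transcription repressor, stood at 1.11 ± 0.18 (SE), a fold of 2.16, with 0.86 on R1, 1.54 on S1 and 1.07 on S2. TUBGCP3, of the gamma-tubulin complex, stood at 1.02 ± 0.19, while a dimmer probe of it stood at 0.01. The others besides TRIB3 were PRXL2C (0.85 ± 0.16), N4BP2 (0.83 ± 0.15), the kinetochore gene NUF2 (0.72 ± 0.14), the chromatin remodeller RSF1 (0.70 ± 0.12), the HSP90 co-chaperone CHORDC1 (0.68 ± 0.12), YBX1 (0.63 ± 0.13, and 0.42 without 32 h R1) and INTS13 (0.54 ± 0.10). All of these but TRIB3 lay above 0 on all 3 arrays. CHORDC1 was also the 1 member of the 19 cytosolic heat shock proteins to pass when adjusted over the list alone, against 0 over all genes.

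Among the other genes given at both times, DDIT3 stood at 0.42 ± 0.14 (SE, n = 3) at 32 h, ATF4 at 0.37 ± 0.18, XBP1 at 0.32 ± 0.15 and ASNS at 0.08 ± 0.14. Without 32 h S1 ATF4 and XBP1 each stood at 0.13. DPAGT1 stood at -0.02 ± 0.15, CCND1 at 0.11 ± 0.20 and CDKN1A at 0.17 ± 0.14. KDR stood at -0.05 ± 0.09, VEGFA at 0.04 ± 0.11 and PECAM1 at 0.05 ± 0.11. None passed, and with the swap arrays as labelled the values of HSPA5, ASNS, DPAGT1, CCND1, CDKN1A, KDR, VEGFA and PECAM1 changed sign under at least 1 alternative setting or without 1 array.

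**Figure D3:**
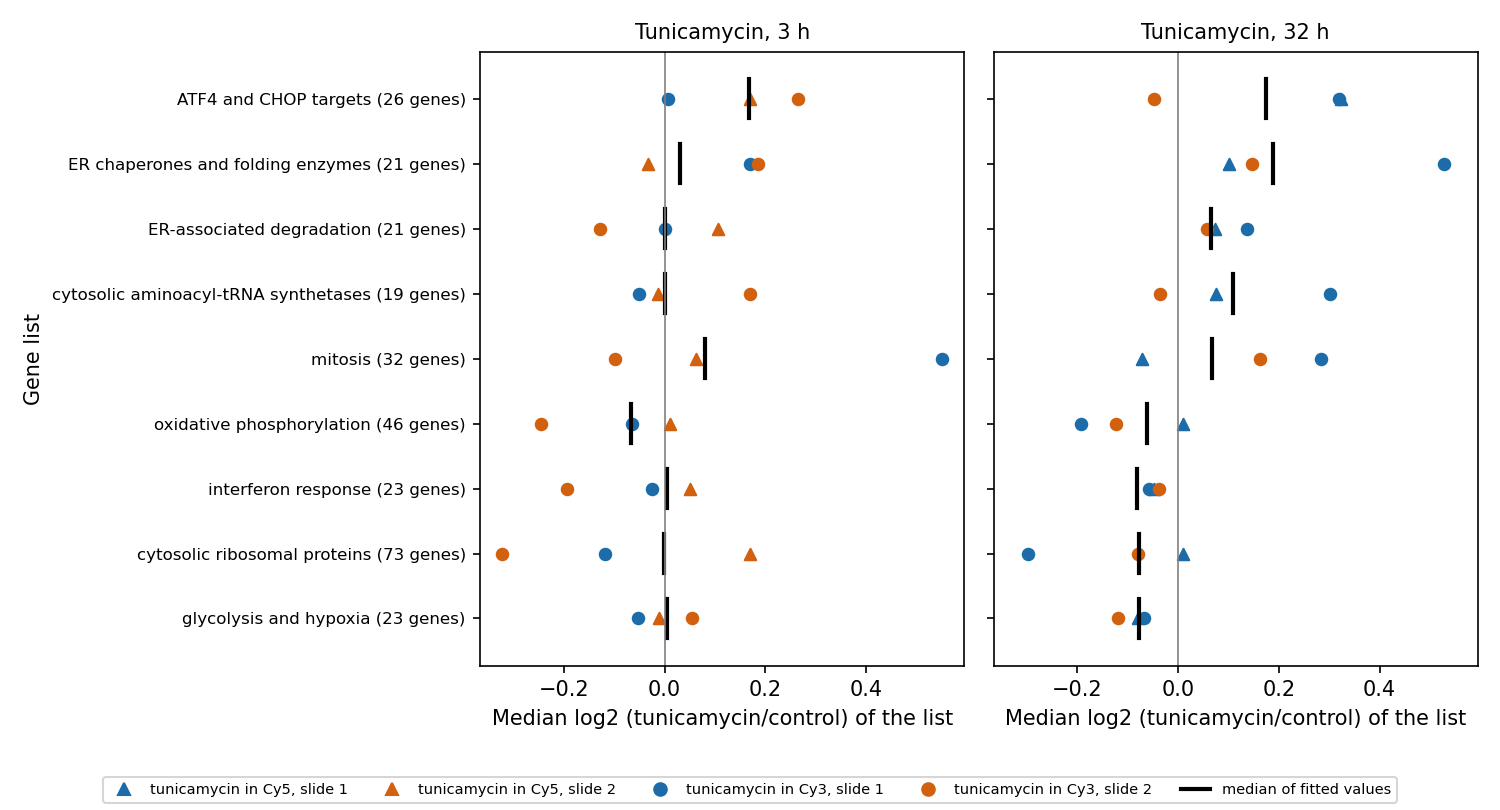
Median log2 ratio of tunicamycin over control of 9 gene lists on each array at 3 h (left) and 32 h (right), with marker shape for the dye of the tunicamycin RNA and colour for the slide. Black bars give the median of the fitted values, 0.17 for ATF4 and CHOP targets at both times and 0.03 at 3 h and 0.19 at 32 h for ER chaperones.

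On average of both times, 5 lists passed by camera. ATF4 and CHOP targets (24 of 26 above 0, median 0.17, adjusted p = 1.9e-13), genes of mitosis (26 of 32, median 0.10, adjusted p = 0.0022) and ER chaperones (16 of 21, median 0.07, adjusted p = 0.0144) rose. The interferon response (median -0.07) and oxidative phosphorylation (median -0.05) fell, each with adjusted p = 0.0041. The list test of the average was not rerun without single arrays. Without each array in turn limma called 0 probes for the average, with from 161 (without 32 h S2) to 531 (without 3 h R2) at an unadjusted p under 0.05. With an estimated correlation the lowest of these lists has adjusted p = 0.671, and fry gave 0.887 for each. TRIB3 was the 1 of the 26 targets to pass adjusted over the list alone, at 0.52 ± 0.07 (SE), against 0 over all genes, and no member of the other lists called here did. In limma 0 probes passed, and 271 had an unadjusted p under 0.05 (203 higher, 68 lower). The share higher, 74.9% here, was 47.3% without 3 h R2, and 50.9% of 4046 such probes with the 4 swap arrays turned.

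The difference between the times was tested directly as 32 h minus 3 h. No list and no probe passed. In limma 0 of 16917 probes passed and 181 had an unadjusted p under 0.05. Camera called 0 lists, with 9 at an unadjusted p under 0.05, and an estimated correlation and fry called 0 as well, each with 0 at an unadjusted p under 0.05. Leaving out 1 array gave from 1 list (without 32 h S1) to 9 (without 32 h S2), with 2 without 32 h R1, 5 without 3 h S1, 2 without 3 h R2 and 7 without 3 h S2. The smallest adjusted p of a list was 0.0545, for genes of autophagy and lysosome, 24 of 33 of which stood higher at 32 h than at 3 h (median difference 0.12). Cytosolic heat shock proteins (median difference 0.11) and glycolysis and hypoxia (-0.15) had adjusted p = 0.0582 each. All 3 of these lists passed with the slide as a random block. That fit sets a common correlation for all pairs of a slide, although turned ratios went together in the same dye and apart in opposite dyes. Autophagy also passed in settings such as no background subtraction and no dye term, heat shock proteins with a dye term for each slide and in the balanced pairs, and glycolysis in the balanced pairs. ER chaperones differed by 0.11 in the median (17 of 21 higher, adjusted p = 0.0858), so their rise at 32 h is not shown to differ from 3 h in this fit. The difference of ER chaperones passed with the slide as a random block, in the dye-balanced pairs and without 32 h S2, and not with the slide as a fixed block or a dye term for each slide. Across probes, the fitted changes at both times correlated with r = 0.22, and the shared dye term links them.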

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

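The tests of a shared dye effect and of wrong swap labels were chosen only after the correlations between arrays had been seen; that of a dye effect of each slide was set before its result, but its outcome followed from those correlations.

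Signals of 2 kinds lie outside the tunicamycin comparisons. The 10 spike-in control probes, RNA added in fixed amounts during labelling, spanned from 5.65 to 5.97 on the log2 scale of Cy5 over Cy3 on every array, and the lowest correlation between a pair of arrays over them was r = 0.989, whatever the dye of the tunicamycin RNA. With the dyes as labelled, the spike-in mixes thus went with the dye and not with the treatment. Were the swap arrays in the orientation of the others, dye and treatment would coincide. The span of the spike-in ratios was alike on all 6 arrays, while the standard deviation of the log2 ratio over probes ran from 0.17 to 0.41. In a fit with a dye term for each slide and the dyes as labelled, 1921 probes had a dye term past the threshold on slide 1 (1120 brighter in Cy5, 801 in Cy3). By limma, 0 passed on slide 2 and 0 for a dye term shared by both slides. No outlier test was made, since each time has 3 arrays.

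Arrays of opposite dye on 1 slide opposed each other once turned to tunicamycin over control. A dye effect shared by all arrays is argued against: as Cy5 over Cy3, arrays of different slides had a median r of 0.0107, against 0.549 within a slide. A dye or labelling effect of each slide stays open: dye terms per slide gave a median residual SD 0.629 times that with a slide term on the turned ratios, but the correlation within slides already implies a ratio under 1, so this decides nothing. That all 4 swap arrays were hybridised in the orientation of the others cannot be told apart from it, because the 68 genes of ER chaperones, ER-associated degradation and ATF4 and CHOP targets had a median of 0.058 on the swap arrays as labelled, with a bootstrap standard error of 0.029 over genes taken as independent, just short of the bound of 2 standard errors. Wrong swap labels predict values below 0, and 48 of the 68 genes lay above 0 there. That count leans against wrong labels, but the genes are not independent and it was not tested. Single genes went both ways: on the 4 swap arrays as labelled TRIB3 lay between -0.13 and 0.00082, and SESN2 between 0.27 and 0.95. With no dye term, 365 probes had an unadjusted p under 0.05 in limma for the average as labelled. With the swap arrays turned there were 4046, and the reason for this rise was not tested. All directions therefore rest on the labels, and a difference between cultures of the biological replicates on each slide stays open and was not tested.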

How the results depend on the processing

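The fit without both swap arrays of slide 2 was chosen only after HSPA5 had been seen below 0 on both, and that with the 4 swap arrays turned only after arrays of opposite dye had been seen to oppose each other.

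Of 1868 comparisons of a named gene's value with an alternative, 1773 kept direction and side of the threshold, 94 turned sign and 1 newly passed (NFIL3 at 32 h, median centring). Of 224 comparisons of a called list, 158 kept the call, 55 lost it and 11 turned. Except where said, the cause was not tested. The strict filter left 13122 probes well above background in both channels on all 6 arrays, and dim probes below it carry the least certain ratios. KDR was well above background with tunicamycin on 1 of 3 arrays at 3 h. The dye-balanced pairs left 2 residual degrees of freedom, fits of each time alone left 1 and give no difference between times, and the array weights (0.256 to 16.3) did not converge.

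Deviations of arrays with the same label number from their time's mean correlated, across probes, with r = 0.56 and 0.44 where tunicamycin was in the same dye and -0.52 and -0.60 where it was in opposite dyes. As labelled, the sign went with the dye and the numbers were not taken to pair the arrays. As Cy5 over Cy3 all 6 pairs on a slide correlated with r from 0.31 to 0.69, so a shared culture or day stays open, and the shared dye term leaves this structure in the residuals. With this number, which is also the slide, as a replicate block, 3 lists passed at 32 h in place of 5, 0 probes passed by limma (28 at 3 h and 417 at 32 h at an unadjusted p under 0.05), and DPAGT1 at 3 h stood at 0.024. As a random block (correlation -0.214), the slide gave 9 lists at 32 h and 7 for the difference, with ATF4 at -0.0038 and XBP1 at -0.015 at 3 h and DPAGT1 at 0.030 at 32 h. This common correlation cannot hold pairs of a slide that correlate positively in the same dye and negatively in opposite dyes, so the added calls carry that limit.

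Lists past the threshold numbered 3 at 3 h, 5 at 32 h and 0 for the difference. At adjusted p under 0.01, 1 passed at 32 h, and under 0.1, 8 passed at 32 h and 7 for the difference. Median centring gave 12 lists at 3 h (10 up, 2 down), 11 at 32 h (8 up, 3 down) and 1 for the difference, with 5 probes at 32 h. No background subtraction, the authors' table, no filter on dim probes, no dye term, array weights, and trend with robust eBayes each gave 1 list for the difference. A dye term for each slide and the mean of a gene's probes each gave 2, and the dye-balanced pairs 7. At 32 h processed signals gave 3 and array weights 0. Without both swap arrays of slide 2, 6 passed at 3 h, 8 at 32 h and 8 for the difference. With an estimated correlation and with fry 0 passed at 3 h and 0 at 32 h, with 1 and 1 at an unadjusted p under 0.05 by the former and 0 and 2 by fry. Leaving out 1 array gave from 3 to 6 lists at 3 h, from 1 to 10 at 32 h and from 1 to 9 for the difference.

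With the swap arrays as labelled, 4 list calls turned: mitosis at 3 h in the balanced pair (adjusted p = 0.4998) and without 3 h S1 (0.655), oxidative phosphorylation at 3 h with median centring (0.784), and ribosomal proteins at 32 h without 32 h R1 (0.569). Over single arrays left out, adjusted p ran from 1.998e-16 to 0.655 for mitosis at 3 h and from 4.83e-05 to 0.569 for ribosomal proteins at 32 h.

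Genes that turned sign with the swap arrays as labelled did so as follows. Without a dye term ATF4 stood at -0.031, XBP1 at -0.12, DPAGT1 at 0.0074 and CDKN1A at -0.055 at 3 h, and DPAGT1 at 0.020 and CCND1 at -0.013 at 32 h. With a dye term for each slide ATF4 stood at -0.030 and XBP1 at -0.051 at 3 h, and DPAGT1 at 0.046 at 32 h. With array weights DPAGT1 stood at 0.12 and VEGFA at -0.058 at 3 h, and HSPA5 at -0.16, ASNS at -0.059 and CCND1 at -0.19 at 32 h. With median centring KDR stood at -0.084 at 3 h, and DPAGT1 at 0.12 and PECAM1 at -0.086 at 32 h. With processed signals PECAM1 stood at -0.091 at 3 h and KDR at 0.046 at 32 h. At 32 h KDR stood at 0.0090 without background subtraction and 0.0089 in the authors' table, and DPAGT1 at 0.11 in the balanced pair. Without both swap arrays of slide 2 DPAGT1 stood at 0.080, CDKN1A at -0.044 and VEGFA at -0.077 at 3 h, and DPAGT1 at 0.11 at 32 h.

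Over single arrays left out, values at 3 h ran from -0.043 to 0.21 for HSP90B1, -0.085 to 0.074 for ATF4, -0.15 to 0.077 for XBP1, -0.13 to 0.080 for DPAGT1, -0.044 to 0.34 for CDKN1A, -0.0045 to 0.075 for KDR, -0.077 to 0.10 for VEGFA, -0.020 to 0.21 for PECAM1, -0.051 to 0.77 for DDIT4 and -0.23 to 0.040 for COX7A2. At 32 h they ran from -0.034 to 0.93 for HSPA5, -0.17 to 0.19 for ASNS, -0.17 to 0.11 for DPAGT1, -0.15 to 0.30 for CCND1, -0.097 to 0.25 for CDKN1A, -0.072 to 0.0059 for KDR and -0.028 to 0.053 for VEGFA.

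With the 4 swap arrays turned and no dye term, 1 list passed at 3 h and 5 at 32 h. Adjusted p was 0.647 for ATF4 and CHOP targets, 0.194 for mitosis and 0.0572 for oxidative phosphorylation at 3 h, all turned. At 32 h it was 0.0347 for ER chaperones, 0.782 for the interferon response, 0.0072 for ribosomal proteins and 0.862 for glycolysis, all turned, and 0.941 for ATF4 and CHOP targets. Genes of opposite sign in that fit were, at 3 h, CREG1 (0.66), SH3BP5L (-0.42), ZNF24 (0.41), PKP4 (-0.39), SUSD2 (0.15), ZBTB22 (-0.076), MYL9 (0.33), MFAP3L (-0.078), ASNS (-0.092), CCND1 (0.52), VEGFA (-0.087), SESN2 (-0.021), CEBPB (-0.088), DDIT4 (-0.33), KIF20A (-0.54), PLK1 (-0.46), BUB1B (-0.65), CDKN3 (-0.32), NDUFA5 (0.28), COX6B1 (-0.17), ATP5PF (0.19) and COX7A2 (0.24). At 32 h they were NFIL3 (-0.58), RSF1 (-0.35), INTS13 (-0.31), N4BP2 (-0.15), TUBGCP3 (-0.10), NUF2 (-0.57), HSP90B1 (-0.22), ATF4 (-0.0050), KDR (0.13), VEGFA (-0.020), PDIA4 (-0.66), DNAJC3 (-0.10), PSPH (-0.31), SESN2 (-0.31), ISG15 (0.064), UBA7 (0.066), PSMB9 (0.61), RPL7A (0.36), RPL3 (0.13), RPS3 (0.40), ALDOC (0.22), PFKFB4 (0.13) and SLC2A1 (0.19). The alternative's own construction turns the sign of 4 arrays.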

Other observations

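The fit with the 4 swap arrays turned and the tests of dye bias in the ATF4 and CHOP targets and of small p-values at 3 h were chosen only after the results they bear on had been seen; those of other ways to turn or split the arrays and of the estimated correlation were set before.

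Endothelial identity and the angiogenic program showed no shift that passed with loess and the shared dye term. The 22 endothelial markers and receptors measured, of 33 listed, had medians of 0.02 at 3 h and -0.03 at 32 h (camera adjusted p = 0.750 and 0.414), and the 36 angiogenic factors and matrix proteases -0.01 and -0.02 (0.719 and 0.548). Among the markers, KDR and PECAM1 were dim (mean log2 intensity 6.91 and 7.06), where the offset draws ratios towards 0, so a shift in them could be missed. Extracellular matrix genes had adjusted p = 0.719 and 0.518, with COL1A1 at -0.47 ± 0.16 (SE) at 32 h, from -1.44 on R1, 0.15 on S1 and 0.67 on S2. Inflammatory NF-kB targets (0.860 and 0.804), immediate early genes (0.303 and 0.565), apoptosis regulators (0.860 and 0.804), cyclins D, CDK inhibitors and p53 targets (0.303 and 0.545) and genes of DNA replication and G1/S (0.719 and 0.804) did not pass either. At 32 h CXCL8 stood at 0.39 ± 0.13, KLF4 at 0.39 ± 0.13 and MDM2 at 0.50 ± 0.15, none past the threshold. These single genes were chosen after their values were seen. Under median centring, which called 12 lists at 3 h and 11 at 32 h, immediate early genes, cyclins D and p53 targets, and extracellular matrix passed at 3 h and endothelial markers at 32 h. DNA replication passed at 3 h with array weights and without 3 h S2. With the 4 swap arrays turned, endothelial markers (median 0.12, adjusted p = 0.0375), DNA replication (-0.28, 0.00011) and cholesterol synthesis (-0.29, 0.00045) at 32 h and ribosomal proteins at 3 h (0.22, 3.6e-10) passed by camera.

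Of the secretory pathway, the 42 genes of N-glycosylation had medians of 0.01 and 0.04 (adjusted p = 0.857 and 0.321), the 45 of ER translocation and COPII/COPI traffic -0.05 and 0.03 (0.719 and 0.128), and the 15 sensors and regulators of the unfolded protein response -0.01 and 0.07 (0.857 and 0.0999). Cholesterol synthesis (0.860 and 0.127) had HMGCS1 at -0.49 ± 0.18 and MVK at -0.47 ± 0.12 at 32 h, with -1.12 and -1.07 on R1 and values between -0.08 and 0.09 on S1 and S2. Cytosolic heat shock proteins (0.303 and 0.179), the oxidative stress response (0.750 and 0.565) with HMOX1 at -0.71 ± 0.22 at 32 h, and autophagy and lysosome (0.140 and 0.127) did not pass at 3 or 32 h with loess and the shared dye term. Other settings called some of these. Cholesterol synthesis passed at both times without 3 h R2 and without 3 h S2. At 32 h it was lower in both fits, but at 3 h it was lower without 3 h R2 and higher without 3 h S2. Autophagy passed at 3 h with array weights and without 3 h S2, and sensors of the unfolded protein response at 32 h without 3 h R2. Heat shock proteins and ER translocation passed at 32 h with a dye term for each slide and without 32 h R1. At 3 h adjusted p was 0.750 for ER chaperones, 0.860 for ER-associated degradation, 0.921 for aminoacyl-tRNA synthetases, 0.303 for the interferon response, 0.955 for ribosomal proteins and 0.921 for glycolysis and hypoxia, and at 32 h 0.128 for mitosis and for oxidative phosphorylation. At 32 h mitosis passed with a dye term for each slide (0.0039), no dye term, median centring, the slide as a random block and without 3 h S1, and oxidative phosphorylation with no dye term. At 3 h the interferon response passed in the balanced pair and without 3 h S1, ribosomal proteins without 3 h S2, and median centring called both with ER chaperones, synthetases and glycolysis. Median, mean and camera's direction did not share a sign at 3 h for ER-associated degradation, sensors of the unfolded protein response, N-glycosylation, DNA replication, extracellular matrix, the interferon response (median 0.01, mean -0.06), cholesterol synthesis and the markers of fibroblasts, chromaffin and cortex cells. At 32 h this held of extracellular matrix and the oxidative stress response. On average of both times it held of ER translocation, DNA replication, extracellular matrix, heat shock proteins, autophagy and the markers of chromaffin cells and leukocytes. For 32 h minus 3 h it held of cyclins, apoptosis, angiogenic factors, NF-kB targets and the lymphatic markers.

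Markers of other cells of the adrenal gland and of vessels did not move with treatment past the threshold with loess and the shared dye term, while median centring called the lymphatic markers at both times. Adjusted p at 3 and 32 h was 0.750 and 0.348 for smooth muscle and pericytes, 0.959 and 0.348 for fibroblasts, 0.921 and 0.772 for chromaffin cells, 0.921 and 0.518 for cortex cells, 0.832 and 0.692 for leukocytes and 0.548 and 0.565 for lymphatic endothelium.

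ATF4 and CHOP targets stood higher with tunicamycin at both times. Of the 30 ways to turn the 6 arrays that can be fitted, the labelled one alone gave as large a shift (1), with a mean z of the list 1.35 from that of all genes against 1.25 for the highest other. The arrays of a slide go together as Cy5 over Cy3 (median r = 0.549), whatever the reason, so the ways to turn them are not alike without a treatment effect, and chance stays open. Dye bias of the list's genes, if alike on both arrays, cancels in the dye-balanced pair of a time. As labelled the list stood there above other genes by 0.201 at 3 h and 0.278 at 32 h, and such a bias would not leave these shifts. Noise between arrays stays open as their source, since 1 pair gives no spread between arrays. The SE of 0.036 and 0.047 are over genes taken as independent. Correlation between the genes on the list stays open, as the higher adjusted p with an estimated correlation was 0.978, so that an induction of these genes by tunicamycin is a hypothesis that these tests left unsettled, and it holds only for the dyes as labelled.

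Probes at 3 h had fewer small p-values than chance gives (0.378% with an unadjusted p under 0.05). A dye effect of each slide that stays in the residuals may account for this, since with a dye term for each slide the share was 6.46%, although limma again called 0 probes, with 1093 at an unadjusted p under 0.05. Wrong swap labels would be taken up by the same terms and are not told apart from it.

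For the counts of probes, the 4 ways to turn the arrays of 1 time are too few for a share under 0.05: all 4 gave at least the real count of 0 at 3 h and at 32 h, with 0 as the highest other count at each. The same holds of the 10 splits of the arrays into times, all 10 of which gave at least 0, again with 0 as the highest other. On average of both times the real count was 0, so all 30 ways give at least as many by construction and say nothing of chance, and the highest other count was 18, with 3 h S1 and 32 h S1, the swap arrays of slide 1, turned. By limma at an unadjusted p under 0.05, the split of 32 h R1, 3 h S2 and 32 h S2 against the rest gave 4483 probes. The real times gave 181, and the split by slide of the turned ratios gave 300. Once the turning is undone, the split with 4483 probes sets slide 1 against the other slide as Cy5 over Cy3. It thus points to a structure of the slides, whose arrays correlated as Cy5 over Cy3 with r from 0.31 to 0.69. The 300 probes do not speak against the slide as its source, and the reason for it was not tested here.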
